A study of Mus musculus with 9 samples.

How the data were processed

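RNA was measured in 9 libraries of mouse medullary brainstem, 4 from animals injected in the cortex with AAV2-GFP and 5 with AAV2-hIL-6. Per the labels' protocols, punches with the raphe nuclei were kept in a stabilising solution, RNA was isolated on columns, and poly(A) libraries were made with a strand-specific kit. Per the submitters' processing notes, kallisto, DESeq2 and the genome build mm10 were used; versions and the gene annotation are not given in the sources used here. The values are FPKM as deposited by the authors, 1 column per library, with no pooling. Library sums of FPKM lay between 567971 and 635729 while their medians lay between 5.70 and 6.02 FPKM and their upper quartiles between 19.3 and 19.6 FPKM. How the libraries were scaled is not given in the sources used here. kallisto assigns fragments to transcripts by likelihood, so a gene listed at 0 can be a failed estimate. Clasrp was listed at 0 in hIL-6 library 2 and at 0.342 to 4.26 FPKM in the others, and Atxn1l was listed at 0 in hIL-6 library 5 and at 0.454 to 3.11 FPKM in the others. Levels of genes with near-identical copies, among them ribosomal protein genes and their pseudogenes, are uncertain for the same reason.

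Depth was read from low values of genes with 1 annotated transcript, which were whole multiples of a step that scales with transcript length. Within a tolerance of 0.05, between 96.8% and 98.0% of these values were whole, where 10% would be by chance for a step fixed in advance. The step and a length offset were chosen in each library to give the highest share. The chance level of that search is above 10% and was not measured. The steps gave 31.5 to 46.4 scaled fragments per library in units of 1e6, a relative measure. Fragments could be recovered for such genes but not for genes with several transcripts, so no count test was run. A match of gene symbols to GENCODE M21, which is built on GRCm38 (the assembly mm10), found 16429 of 17187 symbols, and coordinates are from that annotation. No pair of libraries held identical values.

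Genes with a mean of at least 0.5 FPKM over all libraries were tested, 13958 in all. Values were transformed to log2(FPKM + 0.5), and a fold change on this scale understates the change of low genes. The comparison of hIL-6 with GFP was fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend, batch as a term, two-sided moderated tests and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. The fit had 6 residual degrees of freedom. Group means and SDs in FPKM are over all libraries of a group, without the batch term that the log2 fold changes hold. The batch term and the treatment by batch interaction were tested in the same way. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 36 lists with at least 3 measured genes. The lists, 37 in all, covered cell types of the brainstem, neurotransmitter classes, cytokine and injury responses, growth signalling, metabolism and markers of position. The list of sex-linked genes had no measured member after the filter and was not tested. Several lists share members, such as Serpina3n, which is in the complement, STAT3 and reactive astrocyte lists, and Gfap, which is in the last pair. A list score is the mean over its genes of log2(FPKM + 0.5) centred on the mean of all libraries. An exact permutation test, two-sided, compared list scores over the 60 arrangements that keep the number of hIL-6 libraries in each batch.

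Lists, filters, the rule for named genes and all tests above but the exact permutation of list scores were fixed before the data were examined. The rule took all genes past the threshold up to 15 in each direction, then the genes with the smallest p up to 10 in each direction, stated as not passing. It also took the 4 members with the smallest p of each list with a camera call, up to 2 of other lists, and always Tph2, Slc6a4, Fev, Socs3, Stat3, Il6st, Il6ra, Gfap, Atf3, Gap43, Aif1 and Cd68. Some genes that the rule takes are not reported here. Predicted genes and pseudogenes were to be named only if fewer than 5 others passed, which was the case.

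The procedure was tested on simulated data for the hIL-6 and GFP comparison with the same design, 13958 genes and the moderated spread of each gene. Of 67 genes changed by 0.5 on the log2 scale it called 67.2%, of 67 changed by 1 it called 89.6% and of 66 changed by 2 it called 100%, with 7 unchanged genes among 188 calls. A list of 17 further genes shifted by 0.35, whose members make up the rest of the 188 calls, passed by camera, and an unshifted list did not. Simulated genes varied independently, which genes in tissue do not. Many genes were changed at once, which eases Benjamini-Hochberg adjustment. In the real data C4b and Gfap, with log2 fold changes of 2.76 and 1.86, had adjusted p = 0.18 and 0.90 by limma. The shares called in the simulation therefore set no limit on changes in these data. Alternatives were other pseudocounts and filters, other scalings, no batch term, batch 1 alone, the replicate number as a block, library weights, other variance models, other list tests and each library left out in turn. A term for sex was not fitted, as the Y-linked genes were near the floor in each library (Ddx3y at 0.00989 to 0.288 FPKM, Uty at 0.0316 to 0.226 FPKM and Kdm5d at 0.185 to 0.272 FPKM), and a count test was not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.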

Results

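Poly(A) RNA was sequenced from punches of mouse medullary brainstem that included the raphe nuclei, the brainstem cell groups that hold serotonergic neurons. Wild-type mice had received, 3 weeks earlier, stereotactic injections into the cortex of an adeno-associated virus of serotype AAV2. The virus carried either green fluorescent protein (GFP, the control) or hIL-6, hyper-interleukin-6, a designer cytokine that joins interleukin-6 to its soluble receptor and acts on cells through the shared receptor subunit gp130 and the transcription factor STAT3. There were 9 libraries, 4 of the GFP group and 5 of the hIL-6 group. Batch 1 held 3 GFP and 3 hIL-6 libraries, and batch 2 held 1 GFP and 2 hIL-6 libraries. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries. The table lists 17187 gene symbols in FPKM, fragments per kilobase of transcript and 1e6 fragments. Depth, read from the step between low values, was 31.5 to 38.6 in batch 1 and 38.6 to 46.4 in batch 2, in units of 1e6 scaled fragments. At 0.5 FPKM a 2000-nucleotide transcript then rested on 29.0 to 42.4 fragments, a counting error of 15.4% to 18.6%. Correlations of log2 levels between libraries were 0.97 to 0.99.

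The comparison of hIL-6 with GFP asks how the brainstem transcriptome differed after cytokine delivery to the cortex. Microglia genes were higher in the hIL-6 libraries. All 17 measured genes of the homeostatic microglia list had a positive log2 fold change, with a median of 0.36. None of the 17 passed adjustment over all genes, and 12 passed when adjusted over the list alone. Within batch 1 alone 15 of the 17 were above 0, and Sall1 and Tyrobp were below. Tyrobp was listed at 0 in 6 libraries, at 2.38 FPKM in GFP library 3 and at 4.69 and 16.3 FPKM in hIL-6 libraries 4 and 5. Without Tyrobp the median was 0.36. Cx3cr1, the fractalkine receptor of microglia, was at 8.66 ± 0.18 FPKM (SD, n = 4) in GFP and 11.4 ± 0.53 FPKM (SD, n = 5) in hIL-6 libraries. Olfml3 was at 3.54 ± 0.44 FPKM in GFP and 5.64 ± 0.54 FPKM in hIL-6 libraries. Fcrls was at 6.37 ± 0.58 against 9.80 ± 1.29 FPKM, and P2ry12, the purinergic receptor of resting microglia, at 6.66 ± 1.03 against 9.87 ± 2.20 FPKM. Aif1, the gene of the microglia marker Iba1, was at 4.97 ± 0.88 against 5.81 ± 0.55 FPKM and did not pass either adjustment. The list rose as a set by camera with a preset correlation (adjusted p = 8.09e-24), with adjusted p = 0.358 with an estimated correlation. Permuting the groups within batches gave an exact p = 0.0333 for the mean level of the list over 60 arrangements, and adjusted p = 0.6 over the 36 lists. With 60 arrangements the exact p cannot fall under 0.0167, so 1 list alone could not adjust under 0.6. In the fit on batch 1 alone, where Tyrobp fell under the filter, the median of the other 16 was 0.29.

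Genes of activated microglia and macrophages were also higher as a set, with 13 of 16 measured members above 0 and a median log2 fold change of 0.27. The list rose by camera (adjusted p = 8.78e-07), with adjusted p = 0.399 with an estimated correlation and an exact permutation p = 0.2. Fcgr2b, the inhibitory receptor for immunoglobulin G, was the 1 member that passed when adjusted over the list alone, and none passed over all genes. It was at 1.36 ± 0.13 FPKM in GFP and 4.44 ± 1.39 FPKM in hIL-6 libraries. Ly86 was at 9.05 ± 1.13 against 13.02 ± 2.67 FPKM, Fcgr1 at 0.92 ± 0.16 against 1.31 ± 0.10 FPKM and Fcgr3 at 6.92 ± 0.66 against 9.31 ± 1.88 FPKM. Cd68, a lysosomal marker of phagocytes, was at 3.57 ± 0.74 against 4.43 ± 0.34 FPKM.

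Complement and acute phase genes were higher as a set too. C4b, complement component 4, was at 4.85 ± 3.003 FPKM in GFP and 34.8 ± 14.3 FPKM in hIL-6 libraries, a log2 fold change of 2.76 ± 0.39 (SE) on the log2(FPKM + 0.5) scale. Serpina3n, a serine protease inhibitor, was at 23.8 ± 3.05 against 56.6 ± 15.6 FPKM (log2 fold change 1.18 ± 0.21). The initiating complement subunits C1qa and C1qb were at 38.2 ± 3.80 and 37.9 ± 4.28 FPKM in GFP and at 51.8 ± 6.24 and 50.4 ± 5.63 FPKM in hIL-6 libraries. Of 14 measured members 11 were above 0, and the median was 0.16. Among these C3 and Cfb were near 0, with log2 fold changes of 0.015 and 0.0013. The members below 0 were C2, Cp and Lcn2, at -0.27, -0.083 and -0.21. C4b, Serpina3n, C1qa, C1qb and C1qc passed when adjusted over the list alone, and none over all genes. The list rose by camera (adjusted p = 2.60e-05), with adjusted p = 0.399 with an estimated correlation and an exact permutation p = 0.117. Its median depended on single libraries, at 0.34, 0.047, 0.46 and 0.058 without GFP libraries 1, 2, 3 and 4 and at 0.35 and 0.38 without hIL-6 libraries 1 and 2.

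Response genes of STAT3 and gp130 were higher in 20 of 24 measured members, with a median log2 fold change of 0.19. Gfap, the intermediate filament of astrocytes, was at 116 ± 81.1 FPKM in GFP and 364 ± 123 FPKM in hIL-6 libraries (log2 fold change 1.86 ± 0.44). Gfap, Serpina3n and Cebpd passed when adjusted over the list alone, and none passed over all genes. Cebpd, an acute phase transcription factor, was at 0.98 ± 0.07 against 1.81 ± 0.43 FPKM, and Bcl3 at 0.96 ± 0.67 against 1.99 ± 0.78 FPKM. Socs3, the feedback inhibitor of this pathway, was low at 0.52 ± 0.17 against 1.03 ± 0.46 FPKM, and Stat3 was at 17.9 ± 2.76 against 21.5 ± 3.10 FPKM. The receptor genes Il6st, which encodes gp130, and Il6ra were at 24.9 ± 3.99 and 0.59 ± 0.14 FPKM in GFP and at 27.1 ± 5.19 and 0.89 ± 0.16 FPKM in hIL-6 libraries. The list rose by camera (adjusted p = 4.17e-07), with adjusted p = 0.399 with an estimated correlation and an exact permutation p = 0.05. Its median was 0.32 without GFP library 1, 0.11 without hIL-6 library 1 and 0.30 without hIL-6 library 2.

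Reactive astrocyte genes had a median log2 fold change of 0.20, with 12 of 18 members above 0. Aspg, Serpina3n and Gfap passed when adjusted over the list alone, and none over all genes. Aspg was at 0.64 ± 0.14 against 1.77 ± 0.34 FPKM, and Timp1, a metalloproteinase inhibitor, at 0.33 ± 0.19 against 0.76 ± 0.39 FPKM. The list rose by camera (adjusted p = 0.000465), with adjusted p = 0.615 with an estimated correlation and an exact permutation p = 0.15. Its call was lost without GFP library 4 (median 0.058, adjusted p = 0.144) and without hIL-6 library 3 (median 0.043, adjusted p = 0.0697). The median was 0.13 without GFP library 2, 0.29 without hIL-6 library 2 and 0.12 without hIL-6 library 5. General astrocyte genes did not pass, with a median of 0.011 and adjusted p = 0.499. Among them the water channel gene Aqp4 was at 42.3 ± 5.98 against 53.9 ± 7.68 FPKM and Gpc5 at 22.99 ± 2.31 against 21.2 ± 2.25 FPKM.

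**Figure D1:**
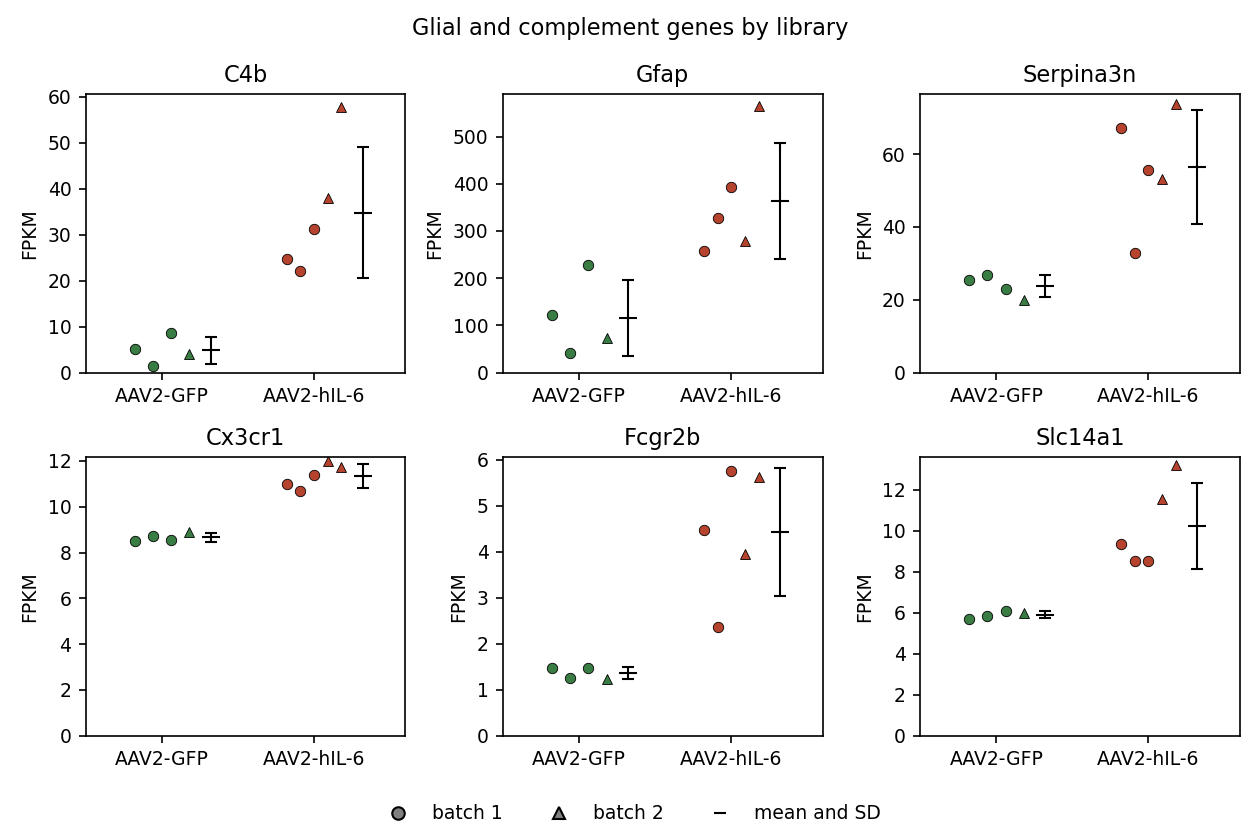
FPKM of 6 genes in each library, with AAV2-GFP and AAV2-hIL-6 libraries on the horizontal axis, circles for batch 1, triangles for batch 2, and bars for the mean and SD. All 5 hIL-6 libraries lie above all 4 GFP libraries for each gene shown, with C4b at a mean of 4.85 FPKM in GFP and 34.8 FPKM in hIL-6 libraries.

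Smaller upward shifts were found in 4 further lists, and no member of any of them passed either adjustment. Oligodendrocyte genes were above 0 in 19 of 20 members with a median log2 fold change of 0.11, and rose by camera (adjusted p = 4.33e-05; adjusted p = 0.615 with an estimated correlation). Trf, transferrin, was at 718 ± 85.8 against 927 ± 176 FPKM, and the myelin genes Cldn11, Mal and Mog were at 217 ± 50.7, 217 ± 31.4 and 173 ± 19.3 FPKM in GFP and at 271 ± 34.6, 253 ± 40.6 and 189 ± 27.0 FPKM in hIL-6 libraries. Without hIL-6 library 3 the median was 0.047 and adjusted p = 0.0615, and without GFP libraries 1 and 3 the median was 0.066 and 0.18. Cytosolic ribosomal protein genes were above 0 in 69 of 76 members with a median of 0.057 (camera adjusted p = 4.17e-07; adjusted p = 0.615 with an estimated correlation), at 0.088 without GFP library 2 and 0.033 without hIL-6 library 3. Among their leading members were Rpl14 (144 ± 14.0 against 155 ± 10.9 FPKM), Rps27l (26.7 ± 2.75 against 29.5 ± 1.70 FPKM) and Rpl13 (279 ± 45.9 against 280.2 ± 52.8 FPKM). Rpl13 was lower in batch 2, by -0.51 on the log2 scale, and its log2 fold change with batch as a term was 0.078. Nuclear genes of oxidative phosphorylation (OXPHOS) were above 0 in 73 of 82 members with a median of 0.048 (camera adjusted p = 4.91e-05; adjusted p = 0.652 with an estimated correlation). Cox8b was at 2.98 ± 0.52 against 5.40 ± 3.81 FPKM, Atp5e at 252 ± 33.5 against 269.7 ± 24.0 FPKM, Ndufs6 at 118 ± 16.6 against 122 ± 14.4 FPKM and Ndufs7 at 146 ± 24.6 against 150.4 ± 25.4 FPKM. The OXPHOS call was lost without GFP library 1 (median 0.022, adjusted p = 0.0966) and without GFP library 3 (median 0.011, adjusted p = 0.221), and the median was 0.10 without GFP library 2 and 0.031 without hIL-6 library 1. Interferon response genes were above 0 in 21 of 26 members with a median of 0.071 (camera adjusted p = 0.0392; adjusted p = 0.615 with an estimated correlation). Lgals3bp was at 9.87 ± 1.57 against 13.3 ± 2.52 FPKM, Ifi27 at 37.4 ± 4.63 against 43.2 ± 4.92 FPKM and Irf9 at 3.62 ± 0.40 against 4.29 ± 0.45 FPKM. The interferon call was lost without GFP library 1 (median 0.037), GFP library 2 (0.052), GFP library 4 (0.10), hIL-6 library 1 (0.076), hIL-6 library 3 (0.044) or hIL-6 library 4 (0.035). Without GFP library 3 its median was 0.12.

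Among the lists that fell, cholesterol synthesis genes were below 0 in 15 of 16 members with a median log2 fold change of -0.10 (camera adjusted p = 1.48e-05; adjusted p = 0.399 with an estimated correlation), and of -0.059 without hIL-6 library 1. None passed over all genes or when adjusted over the list alone. Insig1 was at 75.7 ± 4.21 against 67.8 ± 2.88 FPKM, and Mvd at 12.2 ± 1.14 against 10.7 ± 1.10 FPKM. Choroid plexus and ependymal genes were below 0 in all 6 measured members with a median of -0.25 (camera adjusted p = 0.00492; adjusted p = 0.399 with an estimated correlation). The median was -0.45 and -0.17 with pseudocounts of 0.1 and 1, and -0.13 with no filter. Rarres2 passed when adjusted over the list alone, and none passed over all genes. It was listed at 1.19, 0.95, 2.46 and 0 FPKM in GFP libraries 1 to 4, at 0.265 FPKM in hIL-6 library 1 and at 0 in the other hIL-6 libraries. Ttr, transthyretin of the choroid plexus, was at 5.76 ± 2.92 against 3.04 ± 2.91 FPKM, Clic6 at 0.71 ± 0.14 against 0.50 ± 0.12 FPKM and Enkur at 0.70 ± 0.25 against 0.53 ± 0.26 FPKM. This call was lost without GFP library 2 (median -0.14, adjusted p = 0.296), GFP library 3 (median -0.17, adjusted p = 0.209) or hIL-6 library 1 (median -0.13, adjusted p = 0.0836), and without GFP library 4 the median was -0.39. It was lost as well with a filter at 1 FPKM (median -0.058, adjusted p = 0.238), with weights for each library (median -0.14, adjusted p = 0.198) and without both libraries lowest in serotonergic genes (median -0.14, adjusted p = 0.305).

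Neuronal lists shifted down by small amounts, and no member of the 6 lists in this paragraph passed over all genes or when adjusted over the list alone. Regeneration-associated genes were below 0 in 19 of 26 members with a median of -0.089 (camera adjusted p = 0.00759; adjusted p = 0.399 with an estimated correlation). Gap43, a growth cone protein, was at 201 ± 9.83 FPKM in GFP and 175 ± 19.96 FPKM in hIL-6 libraries. Adcyap1 was at 5.62 ± 0.45 against 4.40 ± 1.01 FPKM, Basp1 at 147 ± 14.2 against 132 ± 12.3 FPKM and L1cam at 36.9 ± 6.37 against 33.3 ± 3.32 FPKM. Atf3, an injury-induced transcription factor, was at 0.45 ± 0.15 against 0.53 ± 0.17 FPKM, with a mean under the filter of 0.5 FPKM, and was not tested. Glutamatergic genes were below 0 in 8 of 10 members with a median of -0.12 (camera adjusted p = 0.00759; adjusted p = 0.399 with an estimated correlation). Slc17a6, the vesicular glutamate transporter of the brainstem, was at 72.7 ± 12.6 against 67.3 ± 10.2 FPKM, Gria1 at 32.2 ± 4.69 against 26.9 ± 4.93 FPKM and Gria2 at 24.0 ± 3.72 against 22.4 ± 1.94 FPKM. Slc17a7 went the other way, at 17.5 ± 14.6 against 36.7 ± 34.4 FPKM. The mean log2 fold change of the glutamatergic list was -0.011, and the exact permutation p of its score was 0.85. Presynaptic genes were below 0 in 15 of 18 members with a median of -0.068 (camera adjusted p = 0.0133; adjusted p = 0.615 with an estimated correlation), among them Rph3a, Unc13a, Rims1 and Vamp2 with log2 fold changes of -0.17, -0.16, -0.15 and -0.091. Pan-neuronal genes were below 0 in 14 of 16 members with a median of -0.034 (camera adjusted p = 0.0208; adjusted p = 0.615 with an estimated correlation), among them Nefm, Scg2, Syt1 and Map2 at -0.14, -0.19, -0.20 and -0.12. Genes of GABA and glycine neurons were below 0 in 10 of 13 members with a median of -0.060 (camera adjusted p = 0.0389; adjusted p = 0.615 with an estimated correlation). Glra1 and Gad1 had log2 fold changes of -0.20 and -0.15, and Pvalb 0.25. Axon guidance genes were below 0 in 19 of 26 members with a median of -0.066 (camera adjusted p = 0.0486; adjusted p = 0.615 with an estimated correlation), among them Slit1, Sema3c, Ntng1 and Epha4 at -0.30, -0.33, -0.13 and -0.14. Each of these 6 calls was lost on leaving out GFP library 1, with medians of -0.082 for regeneration-associated, -0.10 for glutamatergic, -0.015 for presynaptic, -0.031 for pan-neuronal, -0.058 for GABA and glycine and -0.035 for axon guidance genes. Other libraries ended some of them too. Regeneration-associated genes had adjusted p = 0.0714, 0.0577 and 0.129 without GFP library 2, GFP library 3 and hIL-6 library 1, and glutamatergic genes adjusted p = 0.055 without GFP library 4. Without GFP library 4 and hIL-6 library 3 presynaptic genes had adjusted p = 0.133 and 0.318. Pan-neuronal genes had adjusted p = 0.119, 0.0777, 0.495 and 0.06 without GFP libraries 2 and 4 and hIL-6 libraries 3 and 5. GABA and glycine genes had adjusted p = 0.119, 0.604, 0.12 and 0.184 without the same 4 libraries, with a median of 0.0022 without GFP library 4. Axon guidance genes had adjusted p = 0.124, 0.149, 0.197 and 0.0746 without GFP library 3 and hIL-6 libraries 2, 3 and 5. Medians also moved by over 1.5 times without some libraries. For regeneration-associated genes they were -0.052 without GFP library 3 and -0.053 without hIL-6 library 3. For presynaptic genes they were -0.11 and -0.044 without GFP libraries 2 and 4 and -0.033 without hIL-6 library 3. For pan-neuronal genes they were -0.069 without GFP library 3 and -0.085 and -0.0010 without hIL-6 libraries 1 and 3. For GABA and glycine genes they were -0.093 and -0.036 without hIL-6 libraries 1 and 5, and for axon guidance genes -0.037 without hIL-6 library 3. With the replicate number as a block, the pan-neuronal (adjusted p = 0.0521), GABA and glycine (adjusted p = 0.181) and axon guidance (adjusted p = 0.0725) calls were lost. The axon guidance call was lost in 13 of 24 refits, among them the fits with no filter and with TPM rescaling, and the calls lost under other settings are given with the alternatives.

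Serotonergic genes, the markers of raphe neurons, were below 0 in 14 of 17 members with a median log2 fold change of -0.20. No member passed over all genes or when adjusted over the list alone. Tph2, the rate-limiting enzyme of serotonin synthesis in neurons, was at 39.9 ± 12.5 FPKM in GFP and 34.8 ± 14.3 FPKM in hIL-6 libraries. The serotonin transporter gene Slc6a4 was at 27.2 ± 8.63 against 22.5 ± 9.29 FPKM, and the transcription factor gene Fev at 7.14 ± 2.49 against 5.04 ± 1.71 FPKM. Htr1b, Slc22a3 and Gata3 had log2 fold changes of -0.18, -0.27 and -0.20. The list fell by camera (adjusted p = 0.00794), with adjusted p = 0.632 with an estimated correlation and an exact permutation p = 0.483. The call depended on single libraries, and the size of the shift on hIL-6 library 1 most. Without hIL-6 library 1, the lowest of all libraries for this list with a score of -0.79, the median was -0.012 and adjusted p = 0.969. The call was also lost without GFP library 1 (median -0.16, adjusted p = 0.138), without GFP library 4 (median -0.16, adjusted p = 0.107), within batch 1 alone (median -0.16, adjusted p = 0.0997) and with the replicate number as a block (median -0.17, adjusted p = 0.0513), with medians nearer to that of all libraries. Without GFP library 2 and without hIL-6 library 2 the medians were -0.35 and -0.33. Without both hIL-6 library 1 and GFP library 2, the lowest GFP library for this list with a score of -0.31, the list kept its direction and call. Both libraries were chosen by their scores on this list, so that refit is no support for the call.

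**Figure D2:**
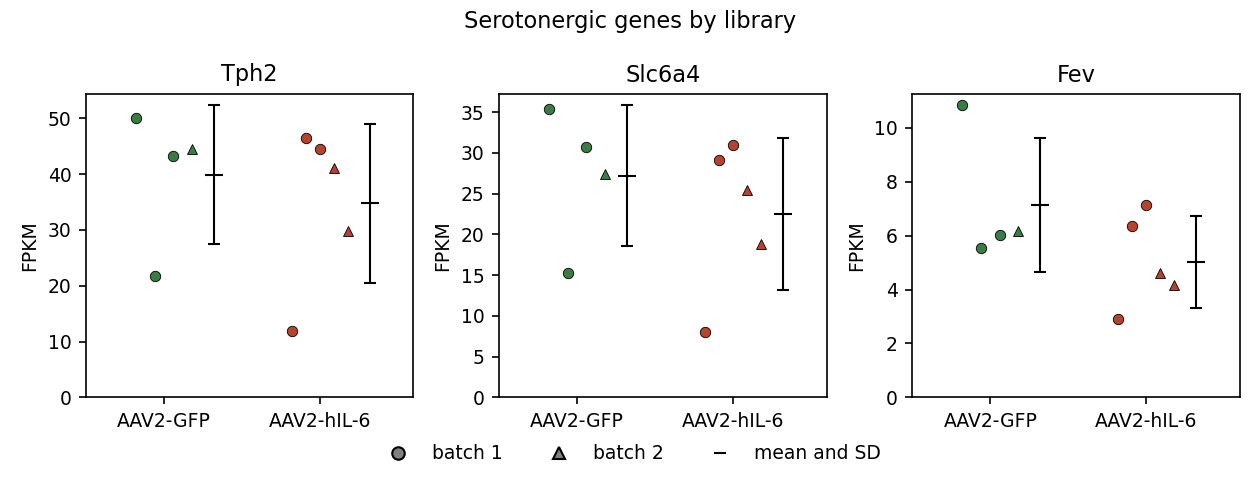
FPKM of Tph2, Slc6a4 and Fev in each library, with AAV2-GFP and AAV2-hIL-6 libraries on the horizontal axis, circles for batch 1, triangles for batch 2, and bars for the mean and SD. The groups overlap for all 3 genes, with Tph2 at 39.9 ± 12.5 FPKM in GFP and 34.8 ± 14.3 FPKM in hIL-6 libraries.

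Gene by gene, 0 of 13958 genes passed adjustment over all genes by limma, and the smallest adjusted p was 0.18. At an unadjusted p under 0.05 there were 543 genes, 346 higher and 197 lower, where chance alone gives 697.9. All 5 hIL-6 libraries lay beyond all 4 GFP libraries for 106 genes, 0.76% of those tested. As many were separated in 27 of the 60 arrangements that keep the batches, the real one included, so this number is not beyond what regrouping the libraries gives. With weights for each library 9 genes passed, all higher (C4b, Slc14a1, Aspg, Cx3cr1, Lgi4, Plscr2, Olfml3, Fcgr2b and Serpina3n), and without hIL-6 library 2 there were 2, Fcgr2b and Serpina3n. The 10 genes with the smallest p among those higher, none passing, were Slc14a1, C4b, Lgi4, Cx3cr1, Aspg, Plscr2, Fcgr2b, Olfml3, the pseudogene Gm12941 and Fcrls. Each was higher in 5 of 5 hIL-6 libraries than in any GFP library. Slc14a1, a urea transporter of astrocytes (GRCm38 chromosome 18, 78100091 to 78142119), was at 5.89 ± 0.17 against 10.2 ± 2.08 FPKM. C4b lies on chromosome 17 (34728380 to 34743882). Lgi4 (chromosome 7, 31059342 to 31070935) was at 13.8 ± 0.25 against 19.8 ± 2.62 FPKM, Plscr2 (chromosome 9, 92275602 to 92297752) at 1.89 ± 0.20 against 3.14 ± 0.32 FPKM and Gm12941 at 1.62 ± 0.27 against 3.59 ± 1.23 FPKM. The 10 genes with the smallest p among those lower, none passing, were Car14, the pseudogene Gm18588, Npcd, Slc27a1, Slc2a8, the pseudogene Gm15427, Apln, Zpr1, Clstn2 and 9930104L06Rik. Car14, a carbonic anhydrase (chromosome 3, 95897768 to 95904691), was at 43.4 ± 4.12 against 35.8 ± 3.31 FPKM, and the fatty acid transporter gene Slc27a1 at 6.08 ± 0.40 against 4.20 ± 1.09 FPKM. Log2 fold changes of the others were -1.08 for Gm18588, -0.97 for Npcd, -0.36 for Slc2a8, -0.44 for Gm15427, -0.20 for Apln, -0.23 for Zpr1, -0.27 for Clstn2 and -0.32 for 9930104L06Rik.

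By camera 18 of 36 lists passed, 9 higher and 9 lower. Other splits of the libraries gave a median of 10 lists by the same test, so a single camera call is weak evidence of a difference between the groups. With an estimated correlation 0 passed and 3 were at an unadjusted p under 0.05. Estimated correlations of the lists with a call lay between 0.071 and 0.65, above the preset 0.01. They were 0.51 for homeostatic microglia, 0.58 for serotonergic, 0.60 for ribosomal protein, 0.61 for OXPHOS and 0.65 for oligodendrocyte genes. The self-contained test fry called 0 lists in 1 direction, and 4 in either direction: the homeostatic microglia (adjusted p = 0.0208), activated microglia (adjusted p = 0.0309), complement (adjusted p = 0.0208) and reactive astrocyte lists (adjusted p = 0.0243). By exact permutation 1 list, homeostatic microglia, had an unadjusted p under 0.05. The exact p of the other lists with a camera call lay between 0.05 and 0.85. It was 0.25 for oligodendrocyte, 0.3 for ribosomal protein, 0.35 for OXPHOS and 0.05 for cholesterol synthesis genes. Without GFP library 1 the camera count was 9. The other 18 lists did not pass. Cholinergic and motor neuron genes had a median of -0.28 over 9 members (camera adjusted p = 0.111). With an estimated correlation, which was 0.74 for this list, adjusted p was 0.698. Within batch 1 alone, at the preset correlation of 0.01, they had a median of -1.48 that passed by camera (adjusted p = 2.99e-15). They also passed with no batch term (median -0.29, adjusted p = 0.0368), without GFP library 4 (median -1.48, adjusted p = 3.60e-14) and without hIL-6 library 4 (median -0.60, adjusted p = 0.0030), and on leaving out single libraries the median ranged from -1.48 to -0.0078. Blood cell genes had a median of -0.34 (adjusted p = 0.111), and passed with no batch term (median -0.36, adjusted p = 0.0498) and without GFP library 3 (median -0.60, adjusted p = 0.0171). Without GFP library 1 their median was 0.032. Medians of the lists above 0 were 0.020 for immediate early, 0.13 for cerebellar neuron, 0.085 for cell cycle, 0.017 for antigen presentation, 0.059 for T cell, B cell and NK cell, 0.032 for heat shock and 0.039 for noradrenergic genes. On leaving out single libraries these ranged from -0.0037 to 0.13 for immediate early, 0.042 to 0.41 for cerebellar neuron, 0.017 to 0.13 for cell cycle, -0.095 to 0.27 for T cell, B cell and NK cell and -0.0019 to 0.079 for heat shock genes. Without hIL-6 library 2 immediate early and antigen presentation genes passed, with medians of 0.13 and 0.11 (adjusted p = 0.0278 and 0.0428), and without hIL-6 library 3 leptomeningeal genes passed, with a median of -0.20 (adjusted p = 0.0126). Those below 0 were -0.036 for PI3K, AKT and mTOR, -0.011 for extracellular matrix, -0.030 for endothelial and mural, -0.049 for neurotrophic factor and -0.0021 for oligodendrocyte precursor genes. Leptomeningeal, Hox and mitochondrially encoded genes had medians of 0.053, 0.0074 and 0.015 while camera placed them lower, at adjusted p = 0.741, 0.942 and 0.992. Hox genes passed within batch 1 alone, with a median of -0.30 (adjusted p = 7.10e-08), and without GFP library 4 with the same median (adjusted p = 4.37e-07). With weights for each library they passed in the other direction, with a median of 0.22 (adjusted p = 0.0164). For endothelial and mural genes the median was below 0 and the mean log2 fold change was 0.0064.

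**Figure D3:**
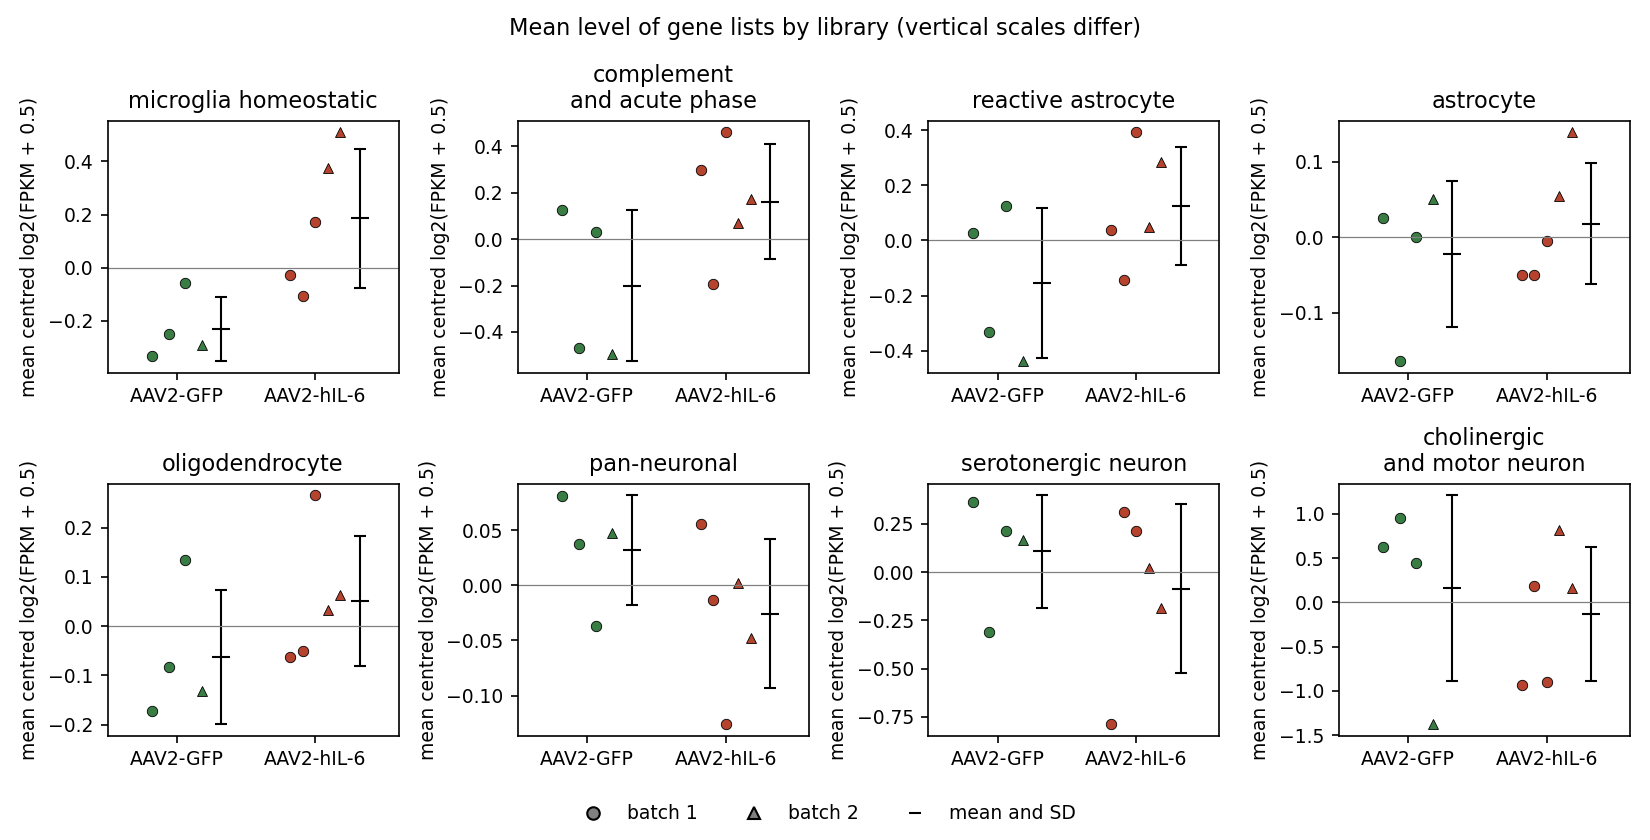
Mean of centred log2(FPKM + 0.5) over the genes of 8 lists in each library, with the groups on the horizontal axis, circles for batch 1, triangles for batch 2, and bars for the mean and SD. Vertical scales differ between panels. Of the 5 hIL-6 libraries 4 lie above all GFP libraries for microglia genes, and serotonergic genes are lowest in hIL-6 library 1 at -0.79.

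The batch comparison describes the difference between the batches named by the labels, and whether it is technical was not tested. Between batch 2 and batch 1, 3138 genes passed by limma, 1585 higher and 1553 lower, and the first principal component, with 32.8% of the variance, separated the batches. The treatment by batch interaction passed for 2 genes, Lxn and Srp54a, with 297 at an unadjusted p under 0.05. Lxn was at 24.5 FPKM in GFP library 4, the only GFP library of batch 2, and at 35.9 to 45.6 FPKM in the other libraries. Srp54a was at 44.7 FPKM in GFP library 4 and at 82.3 and 82.7 FPKM in the hIL-6 libraries of batch 2, and at 57.58 to 64.25 FPKM in batch 1. Both genes were named because they are the whole of that count, after their values were seen.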

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

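The tests on microglia and serotonergic genes and all counts over splits of the libraries were chosen or worded after the results were seen; the test of transcript length was written before, and the share of each shift that the length trend carries was measured after.

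In 260 groups of 4 or 5 libraries, 1 for each named gene or list in each treatment, 12 libraries stood far from the rest of their group, where chance gives about 13. In GFP libraries, Lgi4 was at 14.14 FPKM in library 3 against 13.62 to 13.65 in the others, and Ly86 at 10.73 against 8.411 to 8.598 FPKM. Cldn11 was also high in GFP library 3, at 291.9 against 182.1 to 199.7 FPKM. Fev was at 10.86 FPKM in GFP library 1 against 5.539 to 6.16. The OXPHOS score was 0.173 in GFP library 2 against -0.0985 to -0.0649. In hIL-6 libraries, Mog was at 236.6 FPKM in library 3 against 172.2 to 181.5, and the noradrenergic score was 0.7241 in library 4 against -0.3558 to -0.0445. In hIL-6 library 1, Rarres2 was at 0.2647 FPKM where the others were listed at 0, Enkur was at 0.08681 FPKM against 0.5589 to 0.743, and the cholesterol synthesis score was -0.1645 against -0.0339 to 0.001. Slc17a7 stood high in GFP library 2, at 39.21 FPKM against 7.597 to 12.65, and in hIL-6 library 1, at 97.25 FPKM against 15.2 to 30.81.

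The treatment by batch interaction was 1.083 on the log2 scale for Lxn and 0.9461 for Srp54a. Batch 2 has 1 GFP library, so a differing effect of hIL-6 cannot be told from that library standing apart. For Srp54a the hIL-6 libraries differed too, at 57.58, 59.17 and 59.11 FPKM in batch 1 and 82.3 and 82.71 FPKM in batch 2.

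Counts over splits include the real grouping. Of the 126 splits of the 9 libraries into 4 and 5, 100 were drawn. The count of 0 genes past the threshold was reached by 100 of 100, as any count reaches 0, so this says nothing about chance. The highest other split gave 44 genes. That split put GFP libraries 3 and 4 with hIL-6 libraries 3, 4 and 5, so all of batch 2 lay on its larger side. Batch was a term of the fit, so its contrast rested on GFP library 3 and hIL-6 library 3 against the rest of batch 1. GFP library 3 and hIL-6 library 3 had the highest leptomeningeal scores, 0.92 and 0.87. Whether that difference gave the 44 genes was not tested. Among the 60 splits with the same number from each batch the highest gave 3 genes. The count of 18 lists was reached by 6 of 100 splits, the highest other being 20, so chance cannot be excluded for the number of lists. The other splits had a median of 10 lists, as had those with the same number from each batch. Calls by camera with a preset correlation are thus common under regrouping of these libraries. For batch, the count of 3138 genes was reached by 1 of 84 splits, the highest other being 2, and chance is excluded.

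Microglia genes were higher in the hIL-6 libraries, with a median log2 fold change of 0.36. The fit held batch as a term, so a shift between batches shared by both groups is already taken out of this difference. Permutation within batches gave an exact p = 0.0333, with adjusted p = 0.6 over the 36 lists. It measures regrouping of the libraries and does not test a batch difference. A lower share of neurons would raise the markers of other cell types alike, but the microglia score moved 0.40 beyond the mean score of astrocyte, precursor and endothelial genes (0.3974 on the log2 scale, exact p = 0.0167). Oligodendrocyte genes were higher too, and the microglia score moved 0.2628 beyond their score (exact p = 0.0167). These values argue against a lower share of neurons as the whole cause, provided the other cell types kept their proportions, which was not tested. The microglia list had the smallest camera p of the 36 lists, and these tests were chosen after that was seen. An exact p of 0.0167 is also the lowest that 60 arrangements allow. A part of the shift from a lower share of neurons stays open. Over splits, the mean moderated t of 3.61 for microglia genes was reached by 1 of 100, the real grouping, but the highest other split gave 3.60. Among the 60 splits with the same number from each batch it was again reached by 1, the real grouping, and the highest other gave 2.74, so the margin is narrow over the splits drawn and wider where the batches are kept. Among the splits not drawn a larger value is not excluded. For the reactive astrocyte and the STAT3 lists, 11 and 6 of 100 splits gave a mean t as large as the real 1.32 and 1.49, the highest others being 2.58 and 2.31, and chance is not excluded. Whether hIL-6 delivery raised these genes by the number of microglia or by their expression in each cell was not tested. Tyrobp, listed at 0 in 6 libraries, did not carry the result: without it the score differences were 0.361, 0.377 and 0.242, each with an exact p = 0.0167.

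Serotonergic genes were lower in the hIL-6 libraries by camera with a preset correlation, with a median of -0.20, and did not pass with an estimated correlation (adjusted p = 0.632). Without hIL-6 library 1 the median was -0.0123 and adjusted p = 0.969. The list call was also lost without GFP library 1 or 4, with adjusted p = 0.138 and 0.107. A candidate explanation is that the punch of hIL-6 library 1 held less raphe tissue. Leaving out the lowest library of the lower group shrinks the shift in any case, so this refit cannot decide. Without both libraries lowest in serotonergic genes, GFP 2 and hIL-6 1, the list kept its direction and its call by camera with a preset correlation. Both were chosen by their scores on this list, which narrows its spread within the groups, so the kept call is no support. The preset correlation of 0.01 stands against an estimated 0.58, and the exact permutation p over all libraries was 0.483. An effect of treatment on these genes in the other libraries stays open.

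Ribosomal protein, OXPHOS and cholesterol synthesis genes shifted by small amounts. With the length trend of each library removed, the medians were 0.0387, 0.0284 and -0.1032, and each list still passed by camera (adjusted p = 0.000123, 0.00592 and 2.17e-05). These values met the bound set in advance against a length trend as the whole cause. The length trend itself carried a mean shift of -0.000497 (SE 0.00159) of the -0.107 of cholesterol synthesis genes, so it is excluded as their cause. For ribosomal protein and OXPHOS genes it carried 0.0175 (SE 0.0148) of 0.0529 and 0.017 (SE 0.0142) of 0.0504. The 95% intervals, to 0.0537 and to 0.0518, reach the whole shift, so for these lists a length trend cannot be told apart from other sources. By exact permutation within batches the corrected shifts had p = 0.383 and 0.45 for ribosomal protein and OXPHOS genes and p = 0.05 for cholesterol synthesis genes, so whether the groups differ stays open as well. No biological explanation was tested for this pattern.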

How the results depend on the processing

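Alternatives chosen after seeing the data were the fit without both libraries lowest in serotonergic genes (GFP 2 and hIL-6 1), the punch position covariate (motor neuron and Hox scores), exact permutation within batches and the microglia list without Tyrobp (18 lists passed). No gene passed in any setting except library weights, with 9, and leaving out a library, with 0 to 2 (2 without hIL-6 library 2). Counts of lists were 14 to 18 in the fits on all libraries, on batch 1 alone and without the 2 libraries above, and 9 to 19 on leaving out a library (9 without GFP library 1, 19 without hIL-6 library 2). Adjusted p-values under 0.05 were found for 0 lists with camera at an estimated correlation, 0 with fry in 1 direction (4 in either direction) and 0 by exact permutation. These 3 tests take the correlation between genes from the libraries, where the preset test sets it at 0.01. The exact p cannot fall under 0.0167 with 60 arrangements. A count above 0 by exact permutation would need many lists at that floor, so its count of 0 says little. Interaction calls were 2, with 1 under quantile normalization and 3 with no filter, and batch calls lay between 2777 and 3263. Of 18 lists with a call, 6 kept direction and call in all 24 refits: microglia, activated microglia, complement, STAT3, ribosomal and cholesterol synthesis genes. Some moved by over 1.5 times, with medians of 0.11 and 0.17 for activated microglia with no filter and TPM rescaling, 0.063, 0.26 and 0.058 for complement genes with no filter, a filter at 1 FPKM and batch 1 alone, and 0.029 and 0.026 for ribosomal genes with quantile normalization and no batch term. Cholesterol synthesis genes were at -0.061 with library weights and -0.045 without the 2 libraries above, where ribosomal genes were at 0.096. Of 2102 values of reported genes under alternatives, 2085 kept direction and side of the threshold, 11 passed and 6 turned. Of 859 values of lists, 737 kept both, 71 lost the call, 11 gained it and 40 turned. Replicate numbers 1 to 4 correlated across groups by 0.133, 0.143, 0.269 and 0.457, but numbers 1 to 3 within batch 1 by 0.019, -0.106 and 0.27, and GFP library 2 correlated best with hIL-6 library 1 (0.277); the first values hold the batch, so the samples were taken to share only a number. With the replicate block 0 genes and 14 lists passed, without the serotonergic, pan-neuronal, GABA and glycine and axon guidance lists. The cause of the changes below was not tested. The sex term and the count test were not run.

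For genes the sign turned, and for lists camera's direction, which the median need not follow. With library weights these were Enkur 0.046 and the medians of cholinergic 0.90, leptomeningeal 0.054, Hox 0.22 and mitochondrially encoded genes 0.0175. Without the 2 libraries lowest in serotonergic genes they were Enkur 0.086 and the medians of cholinergic 0.13, astrocyte -0.029, leptomeningeal 0.067, Hox 0.12 and mitochondrially encoded genes 0.029. In batch 1 alone they were extracellular matrix 0.0198 and noradrenergic genes -0.18. With the punch position covariate the medians were 0.0297 for Hox and 0.0264 for mitochondrially encoded genes. Camera's direction for the latter also turned with a pseudocount of 0.1 (0.0154), a filter at 1 FPKM (0.0154), no trend (0.0154), no batch term (0.0497) and the replicate block (0.022). On leaving out each library, Tph2 ranged from -0.55 to 0.089, Slc6a4 from -0.59 to 0.0349, Il6st from -0.0121 to 0.10 and Enkur from -0.47 to 0.0136. Medians ranged from -0.35 to -0.0123 for serotonergic, -0.60 to 0.0317 for blood cell, -0.0282 to 0.11 for antigen presentation, -0.0388 to 0.076 for astrocyte, -0.0748 to 0.0267 for oligodendrocyte precursor, -0.088 to 0.0198 for extracellular matrix, -0.0822 to -0.00861 for endothelial, -0.0767 to -0.00526 for neurotrophic factor, -0.18 to 0.17 for noradrenergic, -0.20 to 0.22 for leptomeningeal, -0.30 to 0.084 for Hox and -0.0288 to 0.0535 for mitochondrially encoded genes.

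Other settings lost calls by limma and camera. Axon guidance genes had adjusted p = 0.0662 with no filter, 0.0728 with TPM rescaling, 0.0624 with quantile normalization, 0.21 with no batch term, 0.0615 with library weights, 0.0581 with no trend and 0.0595 with the punch position covariate. With no batch term glutamatergic genes had adjusted p = 0.193 and GABA and glycine genes adjusted p = 0.112, the latter also adjusted p = 0.0675 with no trend. With library weights regeneration-associated genes had adjusted p = 0.301 and interferon genes adjusted p = 0.0784. Both were also lost with no filter, at adjusted p = 0.0578 and 0.144, and interferon genes with a filter at 1 FPKM, at adjusted p = 0.0505. Without the 2 libraries lowest in serotonergic genes, regeneration-associated, GABA and glycine, and interferon genes had adjusted p = 0.194, 0.105 and 0.283. In batch 1 alone, reactive astrocyte, glutamatergic, presynaptic, pan-neuronal and GABA and glycine genes had adjusted p = 0.15, 0.056, 0.15, 0.09 and 0.559.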

Other observations

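The genes in this part were chosen after their values were seen. Markers of motor neurons differed between libraries of the same group. Chat, the enzyme of acetylcholine synthesis, was at 4.96, 6.95, 4.92 and 0.463 FPKM in GFP libraries 1 to 4 and at 0.866, 3.13, 1.19, 7.61 and 3.96 FPKM in hIL-6 libraries 1 to 5. Hoxb5, a gene of the caudal hindbrain, was at 2.86 FPKM in GFP library 4 and at 12.96 to 16.3 FPKM in the other GFP libraries. The cholinergic score was -1.38 in GFP library 4, -0.93 in hIL-6 library 1 and -0.89 in hIL-6 library 3, and above 0 in the other 6 libraries. The libraries fall into separate clusters on this score, so no correlation is given. A candidate explanation is that punches were taken at different positions. With the punch position covariate the median log2 fold change of microglia genes was 0.36 and 17 lists passed.

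GFP library 2 and hIL-6 library 1 had the lowest serotonergic scores of all libraries, -0.31 and -0.79, and the highest levels of Slc17a7, a vesicular glutamate transporter gene, at 39.2 and 97.3 FPKM. Zic1, a transcription factor gene of cerebellar granule neurons, was also highest in these libraries, at 7.26 and 16.4 FPKM, though hIL-6 library 3 was near the former at 6.99 FPKM.

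Pituitary hormone genes were present in some libraries of both groups. Gh, growth hormone, was at 40.2 FPKM in GFP library 1, 18.5 FPKM in hIL-6 library 4, 4.53 FPKM in GFP library 2 and 1.98 FPKM in hIL-6 library 1, and was listed at 0 in GFP libraries 3 and 4 and hIL-6 libraries 3 and 5. Prl, prolactin, was at 35.1 FPKM in GFP library 1 and 10.98 FPKM in hIL-6 library 4.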
